A study of Homo sapiens with 20 samples.

How the data were processed

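The 20 libraries were 3′ mRNA libraries (QuantSeq, with molecular barcodes) of IMR-32 cells, sequenced as single-end reads. The deposited values are counts, raw and not normalised, for 58787 genes by Ensembl identifier, and they were checked to be whole numbers that differ between libraries. Per the labels the authors used FastQC 0.11.7, STAR 2.7.2b, edgeR 3.36.0 and limma 3.50.3 with the genome build GRCh38. The annotation release, the counting settings, the strand setting and whether the molecular barcodes were collapsed are not given in the sources used here. All 20 columns were used. Gene coordinates came from GENCODE 29, which held 58515 of the identifiers. Gene names came from a separate reference, in which 802 of the tested genes had no symbol.

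Library totals ran from 3960885 to 6537843 counts and detected genes from 18122 to 19951. A count of 0 allows up to 3 counts, 0.757 CPM (counts scaled to a common library total) in the smallest library and 0.459 in the largest; such floors cover counting error only. Between libraries of a group Pearson's r across genes, which are not independent replicates, was 0.976 to 0.985. The chi-square per degree of freedom was 3.01 to 8.46, so no library was a copy of another.

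Groups were taken from the labels, 5 groups of 4 libraries. The comparisons, tests, 24 gene lists, the rule for named genes and alternative settings were chosen before the data were examined. Genes were filtered with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 13729 genes with 99.6% to 99.8% of the counts. Scaling used TMM factors (0.968 to 1.03). One model with a term per group was fitted to all libraries with edgeR 4.0.16 (robust quasi-likelihood fit and F-test, 15 residual degrees of freedom, common biological coefficient of variation 12.5%) in R 4.3.3. The p-values were two-sided and adjusted by Benjamini-Hochberg over all tested genes within each of 8 comparisons, with a threshold of 0.05. Values given with ± beside a log2 fold change are standard errors. CPM values in the text are scaled by TMM, and a prior count of 2 was used for log values.

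The 24 lists held 439 genes, of which 426 were in the table and 354 were tested. The 20 lists with at least 5 tested members were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 and, as an alternative, an estimated one, adjusted over the lists within each comparison. A count adjusted over the list alone applies Benjamini-Hochberg to the members only.

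The rule for named genes took, for each comparison with DMSO, the 6 called genes with the largest rise and the 6 with the largest fall, with a mean log2 CPM of at least 3, a symbol and no overlap between the libraries of both groups. For the other comparisons it took 4 each way, without the overlap condition for the interaction. It also took up to 4 members with the smallest p of each list past camera or with at least 3 called members, and CHEK1, MUS81, EME1, DNM1, DNM2, DNM3, MYCN and CDKN1A throughout. Some genes, and 1 of the 20 tested lists with its results, are not reported here; the adjustment over lists and the counts of lists in the splits include that list. The text names a subset of these, picked after the values were seen. MALAT1 and genes in the closing section outside the rule were also chosen after their values were seen.

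Alternatives were library sizes alone or relative log size factors as scaling, no low-count filter, a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, the compared groups alone, the replicate number as a block, and leaving out each library. A term for replicates 1 and 3 against 2 and 4, and fits within each of these subsets, were added after seeing the data. The replicate numbers are not stated to pair libraries, so this was checked: deviations from the group mean were correlated between groups, and the number was read as pairing where every same-number correlation passed 0.1. That held for the low dose (0.144 to 0.237), prexasertib (0.157 to 0.212), the combination against prexasertib (0.115 to 0.230), against the low dose (0.144 to 0.294) and for the high against the low dose (0.110 to 0.298), where blocked values stand beside the others. It did not hold for the high dose (lowest 0.0271), the combination against DMSO (lowest 0.0274) or the interaction. A miss of this rule, applied to each comparison apart, does not show that the libraries were unpaired. Pairs that correlated best with their own number were 2 of 4, 3 of 4 and 19 of 24 in the same order. Blocked results that changed for these comparisons are given in the part on processing.

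The steps were tested on simulated data in which known genes were changed. For the combination against DMSO 43.3% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 92.4% of those changed 4-fold were called, with 11 false calls among 13504 genes. For the interaction these were 16.4%, 55.2% and 81.8%, with 5 false calls. Among 20 simulated lists of 20 genes, camera called the 1 shifted by 0.4 and 0 of the unshifted ones. The simulated genes varied independently of each other, with no difference between replicates. This therefore does not test camera on genes that vary together, which the estimated correlation allows for. Correlations of fold changes between comparisons that share DMSO were set against 20 simulations with no change. Other splits of the samples matched the number of lists past the threshold in at least 5% of splits for 6 of the 8 comparisons, with values in the closing section; these splits ignore the pairing.

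Reads of near-identical copies cannot be told apart by 3′ tags, so values of HSPA1B, histone genes and small nuclear RNA genes are uncertain, and genes with processed pseudogenes (HSP90AA1, LDHA, PGK1, HSPE1 and PRDX1) could share reads with them. Genes of the mitochondrial genome were not in the table and were not analysed here.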

Results

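The series measured gene expression in IMR-32, an established human neuroblastoma cell line that carries an amplified MYCN oncogene. Neuroblastoma is a childhood tumour of the developing sympathetic nervous system. Adherent cells received vehicle or drug for 24 h in 5 groups of 4 libraries: DMSO, Dyngo-4a at 1 µM (the low dose), Dyngo-4a at 2.26 µM (the high dose), prexasertib at 2 nM, and the combination of Dyngo-4a with prexasertib. The doses inside the combination are not given in the sources used here. Prexasertib inhibits CHK1, the kinase of the replication checkpoint, and Dyngo-4a is known as an inhibitor of the dynamin GTPases of endocytosis. The series title names joint inhibition of CHK1 and MUS81, an endonuclease that cuts stalled replication forks; how Dyngo-4a relates to MUS81 is not given in the sources used here. Each library held between 3960885 and 6537843 counts from a 3′ mRNA assay. Levels are given in CPM, counts scaled to a common library total, and 13729 genes had enough counts to be tested. Nothing in the labels says whether the 4 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries.

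On the first principal component the 4 high-dose libraries lay apart from all others, while the prexasertib libraries overlapped DMSO. The second component separated replicates 1 and 3 from replicates 2 and 4 in 5 of 5 groups. The third component, with 11.3% of the variance, set the 4 combination libraries (20.7 to 34.2) apart from all others, which had negative values. The nuclear RNA MALAT1 took 1.35% ± 0.42 of the counts in DMSO (SD, n = 4), 1.56% ± 0.43 in the low dose, 2.96% ± 0.16 in the high dose, 1.42% ± 0.36 with prexasertib and 2.33% ± 0.54 in the combination. Against DMSO, its log2 fold change passed edgeR's quasi-likelihood test in the high dose (1.13 ± 0.23 SE, adjusted p = 0.00142) and in the combination (0.80 ± 0.23, adjusted p = 0.0439), a shift that accompanied the gene groups described for these conditions.

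**Figure D1:**
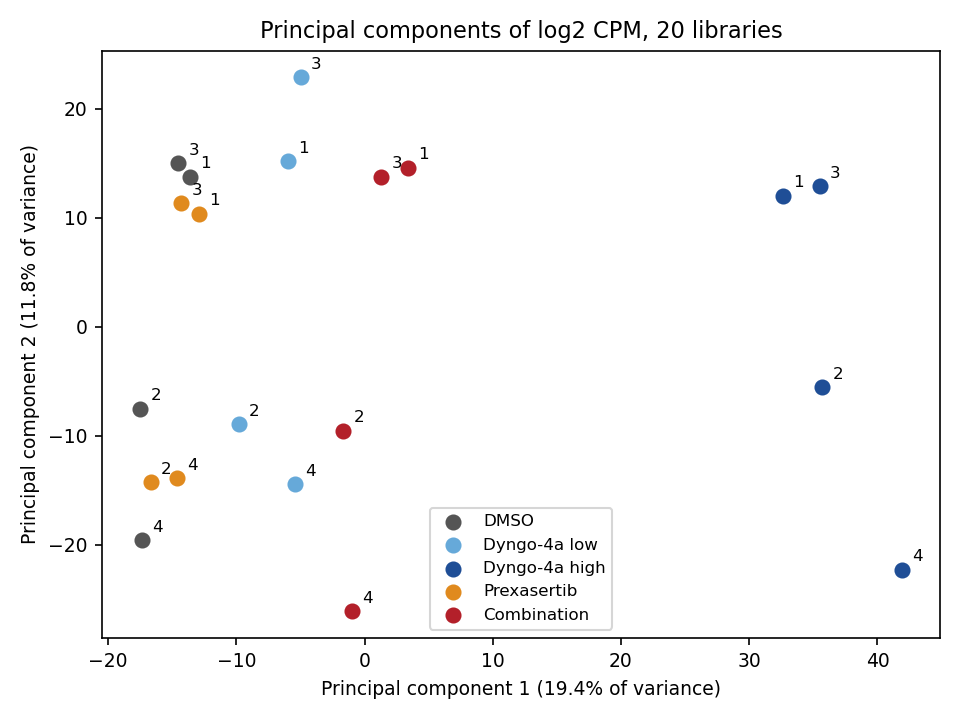
Principal components 1 (x axis, 19.4% of the variance) and 2 (y axis, 11.8%) of log2 CPM in the 20 libraries; each point is a library, coloured by group and numbered by replicate. The 4 high-dose Dyngo-4a libraries lie to the right of all others, and replicates 1 and 3 lie above replicates 2 and 4 in each group.

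The transcripts of the genes at the centre of the design moved little. MUS81 (chromosome 11, 65857126 to 65867653 in GRCh38) measured 52.7 ± 6.8 CPM in DMSO (SD, n = 4) and 47.3 ± 3.2 in the combination, and it was not called in any of the 8 comparisons. Its partner EME1 fell in the high dose (log2 fold change -0.63 ± 0.16 SE, adjusted p = 0.00291) and measured 0.01 in the combination (adjusted p = 0.976). CHEK1, which encodes CHK1 (chromosome 11, 125625136 to 125676255), rose in the high dose by 0.42 ± 0.15 (adjusted p = 0.0389), measured 0.23 in the low dose, -0.02 with prexasertib and 0.04 in the combination, and was not called in those. That high-dose call of CHEK1 was lost when any 1 of 5 libraries was left out (DMSO replicates 1, 2 and 4, high-dose replicates 2 and 4; adjusted p up to 0.220) and with limma-voom (0.0563). Within replicates 1 and 3 alone, a subset chosen after seeing the data, CHEK1 measured -0.02. The dynamin genes DNM1, DNM2 and DNM3 measured 0.04, 0.24 and 0.39 in the high dose against DMSO and were not called (adjusted p = 0.903, 0.0803 and 0.305); DNM2 reached 0.0459 without DMSO replicate 4.

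MYCN (chromosome 2, 15940564 to 15947007), the amplified oncogene of the line, fell in the high dose and in the combination. It measured 1735 ± 149 CPM in DMSO, 1732 ± 132 in the low dose, 1246 ± 58.6 in the high dose, 1808 ± 150 with prexasertib and 1279 ± 144 in the combination (SD, n = 4). Its log2 fold change against DMSO was -0.48 ± 0.09 in the high dose (adjusted p = 0.000156) and -0.44 ± 0.09 in the combination (adjusted p = 0.00159). It measured -0.00 in the low dose and 0.06 with prexasertib, where it was not called.

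**Figure D2:**
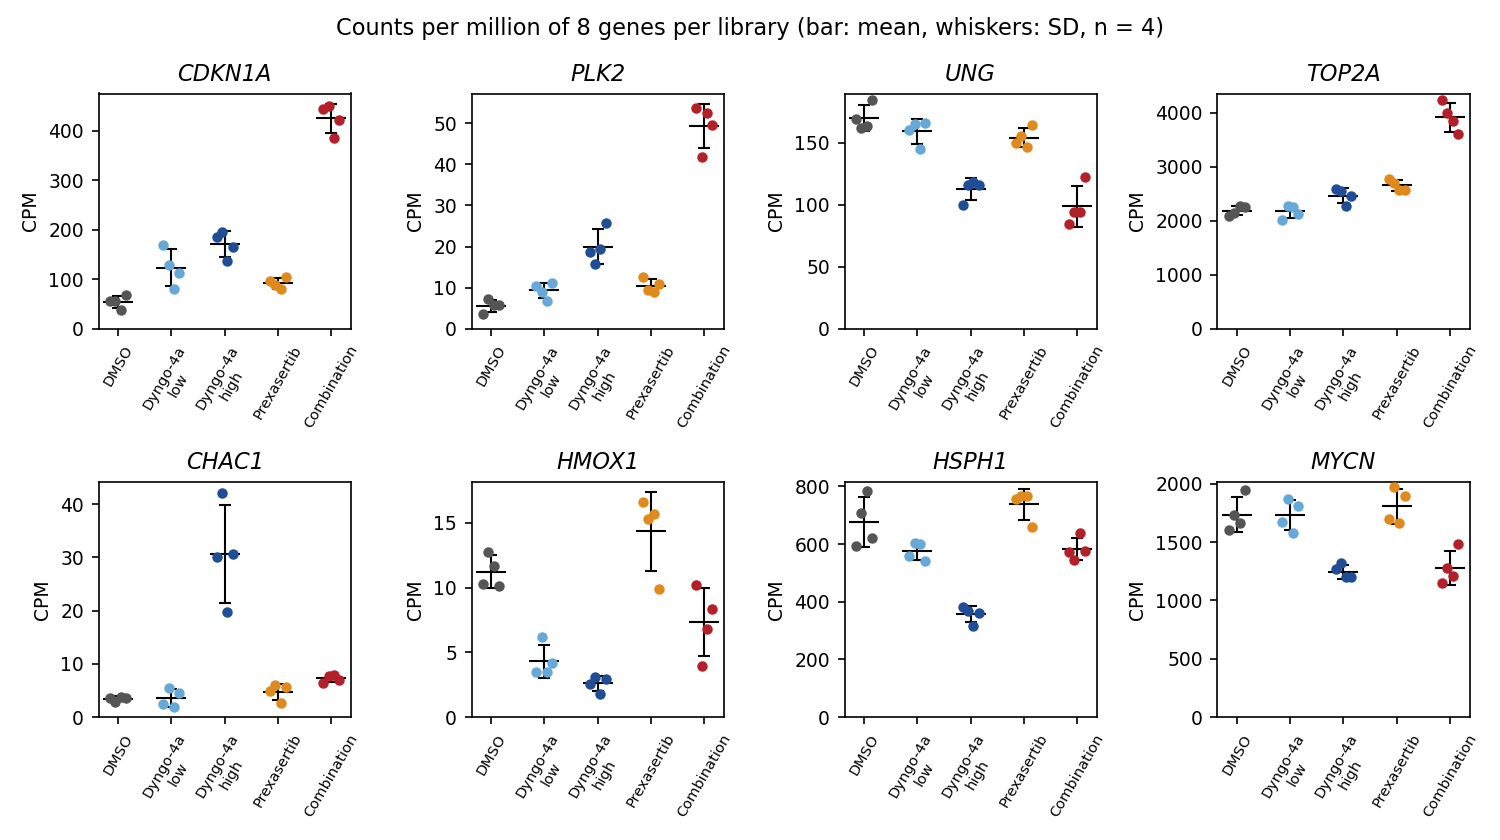
CPM (y axis, linear, from 0) of 8 genes in each library by group (x axis); points are libraries, the bar is the mean and the whiskers are the SD of 4 libraries. CDKN1A reached 425 CPM in the combination against 54.0 in DMSO, while CHAC1 reached 30.6 in the high dose against 3.47 in DMSO.

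The low dose of Dyngo-4a against DMSO asked what Dyngo-4a does alone at the weaker of its 2 doses. It raised genes of the hypoxia response and single genes such as CDKN1A, and it lowered a few antioxidant genes that the transcription factor NRF2 drives. CDKN1A, which encodes the cell cycle inhibitor p21, rose from 54.0 ± 12.4 to 123 ± 37.3 CPM (log2 fold change 1.18 ± 0.19 SE, adjusted p = 0.00566). The noncoding RNA PURPL rose by 2.19, PHLDA3 by 1.08, EDA2R by 1.01 and SESN1 by 1.00. Of 22 hypoxia genes, 5 rose over all genes (7 adjusted over the list alone; median 0.21, camera adjusted p = 7.24e-11). Among them were the glycolytic enzymes ALDOC at 1.91 ± 0.26, PGK1 at 0.72 ± 0.11 and LDHA at 0.62 ± 0.11, and the collagen hydroxylase P4HA1 at 0.79; FAM162A, outside the list, rose by 1.05.

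HMOX1, the haem oxygenase, fell by 1.34 ± 0.26 on the log2 scale (adjusted p = 0.0073). GCLM, a subunit of the enzyme that starts glutathione synthesis, fell by 1.00 ± 0.11 (adjusted p = 9.59e-07), and NQO1 fell by 0.86. These were the 3 of 15 NRF2 targets that fell (4 adjusted over the list alone; median -0.10, camera adjusted p = 3.4e-05, but adjusted p = 0.0814 with an estimated correlation). Of 11 heat shock genes, 0 fell over all genes, 6 fell adjusted over the list alone and 1, HSPA4L at 0.54, rose (median -0.23, camera adjusted p = 4.01e-05, adjusted p = 0.00794 with an estimated correlation). Among them HSP90AA1 measured -0.27 and DNAJB1 -0.45, uncalled at adjusted p = 0.398 and 0.180 but called with the replicate number as a block (0.00434 and 0.00194). The 30 mitotic genes passed as a list towards lower values (median -0.13, camera adjusted p = 2.74e-07) with 0 called by edgeR and 0 adjusted over the list alone. PLK1 and AURKA both measured -0.25, and the list's adjusted p = 0.0649 with an estimated correlation. The 22 cholesterol synthesis genes passed upward with 0 called over all genes or over the list alone (median 0.11, camera adjusted p = 0.00024, adjusted p = 0.144 with an estimated correlation). The proteasome subunit PSMC1 fell by 0.52, the microtubule protein MAP1A by 0.54 and the synaptotagmin SYT2 by 0.66.

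By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 36 genes were called in the low dose, 25 higher and 11 lower, and 260 with the replicate number as a block (121 higher and 139 lower). The count was 62 with no low-count filter (32 and 30). It was 22 without DMSO replicate 2 or 4, 18 without low-dose replicate 1 and 14 without low-dose replicate 3. Leaving out single libraries also ended several calls, with the highest adjusted p in brackets. SYT2 was lost without any 1 of the 8 libraries (0.166). NQO1 was lost without DMSO replicate 1, 2 or 4 or low-dose replicate 1, 2 or 3 (0.165), and SESN1 without DMSO replicate 1 or 4 or low-dose replicate 1, 2 or 3 (0.229). P4HA1 was lost without DMSO replicate 1 or 4 or low-dose replicate 3 (0.0823), and HMOX1 (0.0546) and PSMC1 (0.112) without low-dose replicate 1 or 3. MAP1A was lost without DMSO replicate 1 or low-dose replicate 3 (0.0873), and HSPA4L without DMSO replicate 4 or low-dose replicate 2 (0.0692). With limma-voom PURPL, NQO1 and SYT2 also missed the threshold (0.0597, 0.0553 and 0.0555), and SYT2 missed it with library sizes alone (0.0777). DNAJB1 passed with no low-count filter (0.0253), and fitting only the 2 groups compared ended the calls of CDKN1A (0.148) and SESN1 (0.0776).

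The high dose of Dyngo-4a asked the same question at the stronger dose, and 3456 of the 13729 tested genes passed. It raised the amino acid and stress response genes driven by ATF4, and it lowered heat shock, replication and ribosome biogenesis genes. CHAC1, an enzyme that degrades glutathione, rose by 3.12 ± 0.26 on the log2 scale (adjusted p = 2.72e-11). TXNIP, an inhibitor of thioredoxin, rose by 3.06 ± 0.11 (adjusted p = 8.62e-23), ALDOC by 2.93 and ULBP1, a ligand of a natural killer cell receptor, by 2.80. All 20 tested members of the ATF4 list rose (median 1.28, camera adjusted p = 7.96e-22), including DDIT3, which encodes CHOP, at 2.01, SESN2 at 1.87 and DDIT4 at 1.64; INHBE, outside the list, rose by 2.53.

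CDKN1A rose in the high dose by 1.65 ± 0.19 (adjusted p = 2.3e-06), BBC3, which encodes the killer protein PUMA, by 1.87, PHLDA3 by 1.64 and PURPL by 3.02. In the BCL2 family, 4 of 13 genes rose (4 adjusted over the list alone), with the BH3-only gene HRK at 2.27, and the list did not pass camera (adjusted p = 0.113). Of 12 immediate early genes 4 rose (4 adjusted over the list alone), with EGR1 at 1.47 and JUN at 1.07, and this list did not pass either (adjusted p = 0.123).

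Of 11 heat shock genes 9 fell in the high dose and 1 rose (10 lower adjusted over the list alone; median -0.92, camera adjusted p = 9.06e-11). HSP90AA1 and HSPH1 both fell by 0.92, HSPE1 fell by 1.08 and HSPA1B by 1.57. Replication genes fell in 17 of 29 cases and rose in 2 (19 and 2 adjusted over the list alone; median -0.31, camera adjusted p = 1.79e-07), with the helicase subunit MCM5 at -0.92 and the ribonucleotide reductase subunit RRM2 at -0.72. Ribosome biogenesis genes that MYC proteins drive fell in 11 of 17 cases (12 adjusted over the list alone; median -0.41, camera adjusted p = 1.27e-08), with RRP12 at -0.94 and NOP16 at -0.81. Of 30 mitotic genes 7 fell (8 lower and 1 higher adjusted over the list alone), with HMMR at -1.12 (median -0.16, camera adjusted p = 0.00738, adjusted p = 0.246 with an estimated correlation). The checkpoint genes TIPIN at -0.78 and RPA3 at -0.72 were among 6 of 18 ATR-CHK1 genes that fell while 3 rose (8 and 3 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0632).

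Of 15 NRF2 targets 8 fell and 2 rose in the high dose (9 and 2 adjusted over the list alone; median -0.47, camera adjusted p = 5.47e-05, adjusted p = 0.0747 with an estimated correlation). HMOX1 fell by 2.09, GCLM by 1.73, the thioredoxin reductase TXNRD1 by 0.73 and the peroxiredoxin PRDX1 by 0.67. Cholesterol synthesis genes rose in 10 of 22 cases (10 adjusted over the list alone; median 0.24, camera adjusted p = 5.47e-05, adjusted p = 0.0767 with an estimated correlation), with FDFT1 at 0.69 and HMGCS1 at 0.62. Hypoxia genes rose in 8 of 22 cases and fell in 2 (8 and 2 adjusted over the list alone; median 0.18, camera adjusted p = 0.0113), with VEGFA, the vascular growth factor, at 1.84 and PGK1 at 0.79. Chaperones of the endoplasmic reticulum split, 5 of 15 higher (HERPUD1 at 1.18, XBP1 at 1.02) and 5 lower (SDF2L1 at -0.72, MANF at -0.64), 5 and 6 adjusted over the list alone. Their median was -0.10, their mean 0.08 and the camera adjusted p = 0.907. Identity factors of sympathetic cells split as well, 6 of 16 lower (among them HAND1 at -0.91, HAND2 at -0.56 and MYCN) and 5 higher (TBX2 at 0.70), 6 and 5 adjusted over the list alone, with camera adjusted p = 0.202. Of 20 endocytosis genes 4 rose, with AMPH at 0.79, and 2 fell, with the clathrin heavy chain CLTC at -0.54 (4 and 4 adjusted over the list alone; camera adjusted p = 0.694). The receptor-like gene FGFRL1, the binding protein gene IGFBP5 and the synaptic gene SYNGR4 fell by 1.86, 1.63 and 1.68.

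In all, 3456 genes were called in the high dose, 1715 higher and 1741 lower, of which 304 rose and 192 fell at least 2-fold. No setting chosen before the data were examined moved this count by more than 1.5 times.

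**Figure D3:**
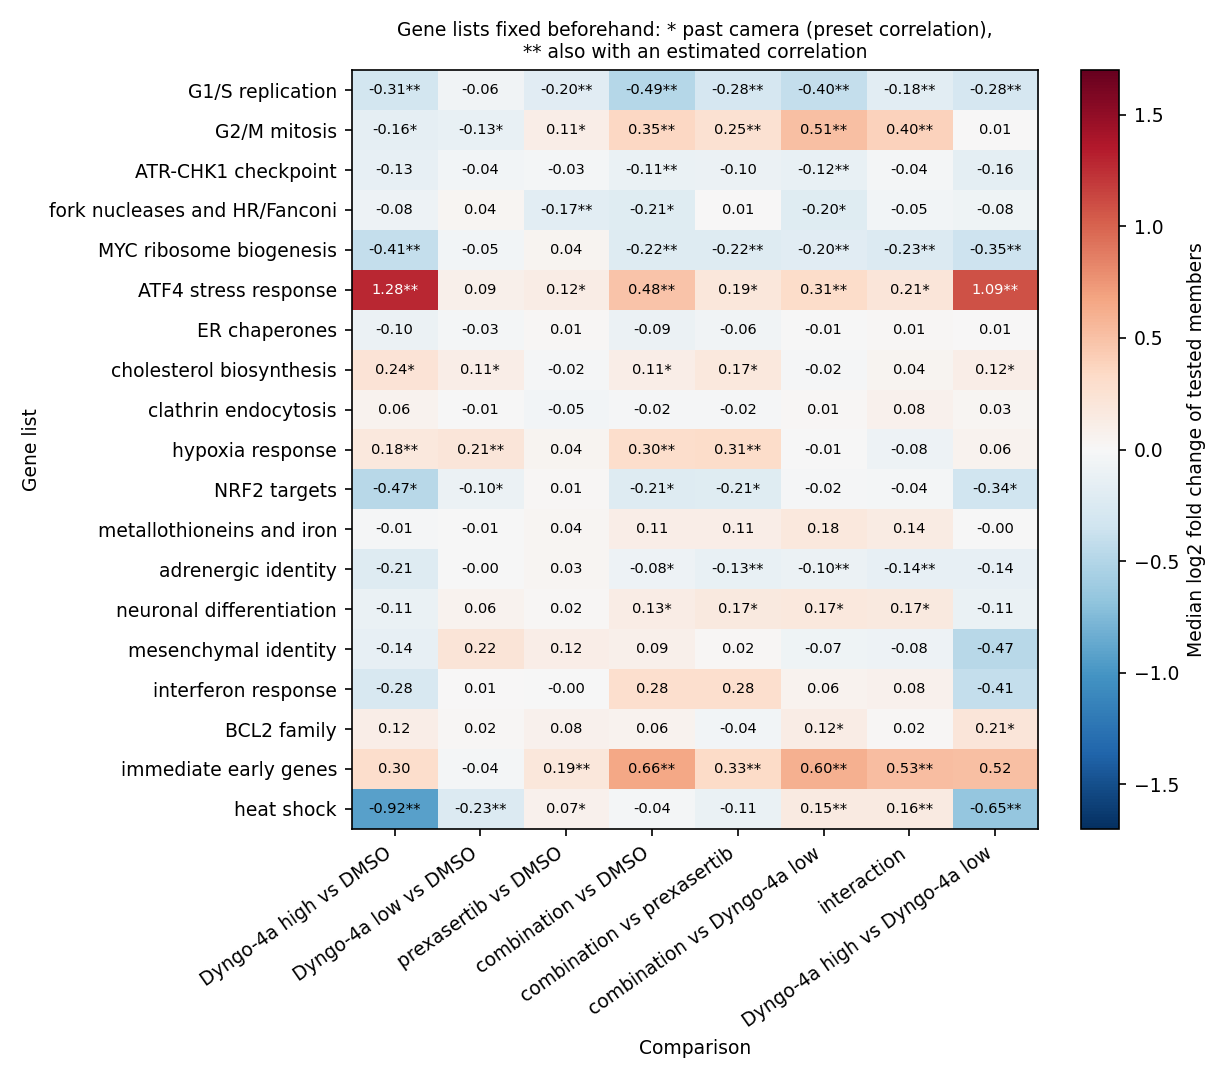
Median log2 fold change (colour and number) of the tested members of 19 gene lists (rows) in 8 comparisons (columns); 1 asterisk marks a list past camera with the preset correlation, 2 asterisks one that also passes with an estimated correlation. The ATF4 list stands at 1.28 in the high dose and 0.48 in the combination, and the replication list at -0.31 in the high dose, -0.20 with prexasertib and -0.49 in the combination.

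The test of the high dose against the low dose asked which changes grew with dose. The ATF4 list separated the doses most clearly by its count. In it, 19 of 20 members were higher in the high dose (19 adjusted over the list alone; median 1.09, camera adjusted p = 2.9e-25), with CHAC1 at 3.03 ± 0.26, the cystine transporter gene SLC7A11 at 2.26 ± 0.16 and DDIT3 at 2.02 ± 0.15. BBC3 was higher by 1.48. Replication genes were lower in 15 of 29 cases and higher in 1, CDT1 at 0.80, with CCNE2 at -1.15 (16 and 1 adjusted over the list alone; median -0.28, camera adjusted p = 2.58e-06). Ribosome biogenesis genes were lower in 11 of 17 cases (12 adjusted over the list alone; median -0.35, camera adjusted p = 2.66e-08). Heat shock genes were lower in 7 of 11 (9 adjusted over the list alone; median -0.65, camera adjusted p = 3.16e-09), with HSPE1 at -1.01. The hypoxia list did not differ by its test (2 higher, 5 lower, camera adjusted p = 0.901): VEGFA was higher by 1.42, while LDHA at -0.52 and the glucose transporter gene SLC2A1 at -0.57 were lower.

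Cholesterol synthesis genes were higher in 8 of 22 cases and lower in 1 (10 and 1 adjusted over the list alone; camera adjusted p = 0.0125, adjusted p = 0.226 with an estimated correlation). NRF2 targets were lower in 5 of 15 cases and higher in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.0125, adjusted p = 0.221 with an estimated correlation), GCLM at -0.73. BCL2 family genes were higher in 4 of 13 cases (4 adjusted over the list alone; camera adjusted p = 0.0243, adjusted p = 0.201 with an estimated correlation, and 0.0531 without low-dose replicate 3). TXNIP, INHBE and ULBP1 were higher by 2.37, 2.59 and 2.65, and LINC01521, PIGW, SYNGR4 and HPDL were lower by -1.86, -1.59, -1.65 and -1.63. MYCN was lower by -0.48 ± 0.09 (adjusted p = 0.000234) and EME1 by -0.56 (adjusted p = 0.0102; 0.0503 without low-dose replicate 3). MALAT1 was higher by 0.94 (adjusted p = 0.0072). The test called 2767 genes, 1382 higher and 1385 lower, and 3980 with the replicate number as a block (1941 and 2039).

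Prexasertib alone against DMSO asked what the CHK1 inhibitor does at its single dose. Shifts were small and shared by members of several lists, with no single gene past the threshold. All 29 replication genes had a negative value (median -0.20, camera adjusted p = 3.65e-20), 5 of them past the threshold adjusted over the list alone and 0 over all genes. FEN1, the flap endonuclease, measured -0.39 ± 0.10, CDC6 -0.37 ± 0.10 and RRM2 -0.31 ± 0.09. CDKN1A measured 0.76 ± 0.19, PHLDA3 0.76 and EDA2R 0.69. The fork and homologous recombination genes lay lower as a list (19 of 21 not positive, median -0.17, 1 past the threshold adjusted over the list alone, camera adjusted p = 4.67e-08), with BRCA1 at -0.33. The immediate early genes lay higher (median 0.19, 1 adjusted over the list alone, camera adjusted p = 0.00222, but 0.0534 without DMSO replicate 3), with EGR1 at 1.35 ± 0.25 (adjusted p = 0.0506).

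Lists of mitotic, ATF4 and heat shock genes passed upward with prexasertib (medians 0.11, 0.12 and 0.07; camera adjusted p = 7.65e-06, 0.00222 and 0.0286; 0, 1 and 1 members past the threshold adjusted over the list alone). Their adjusted p = 0.104, 0.308 and 0.116 with an estimated correlation. TOP2A, the topoisomerase of dividing cells, measured 0.28. Without a single library the ATF4 list missed the threshold for DMSO replicate 3 and prexasertib replicate 2 (adjusted p up to 0.0543). The heat shock list did so for DMSO replicates 1 and 3 and prexasertib replicates 2 and 3 (up to 0.406). The heat shock list also missed it with a filter of at least 1 CPM in 4 libraries. By edgeR 0 genes were called, with 518 at an unadjusted p under 0.05; DESeq2 called 6, limma-voom 0, edgeR with no low-count filter 12, and the fit of only the compared groups 2. The count was 2 without DMSO replicate 2 or prexasertib replicate 4 and 1 without DMSO replicate 4. EGR1 and CDKN1A passed with DESeq2 (adjusted p = 0.00275 and 0.0218) and with no filter (0.000554 for both), TOP2A with DESeq2 (0.0423), PHLDA3 with no filter (0.0288) and CDKN1A in the fit of only the compared groups (0.0398). With the replicate number as a block 23 genes were called, 15 higher and 8 lower, among them EGR1 (adjusted p = 0.00188), CDKN1A (0.0121), PHLDA3 (0.0162), FEN1 (0.00609), CDC6 (0.0444), RRM2 (0.0397), BRCA1 (0.0107) and TOP2A (0.0178). EGR1 also passed without DMSO replicate 2 or prexasertib replicate 4 (down to 0.0374), and PHLDA3 without DMSO replicate 4 (0.0115).

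The combination against DMSO asked what both drugs do together. It raised CDKN1A and mitotic genes and lowered replication genes. CDKN1A rose from 54.0 ± 12.4 to 425 ± 29.3 CPM (log2 fold change 2.97 ± 0.19 SE, adjusted p = 1.5e-09). PURPL rose by 4.19 ± 0.32 (adjusted p = 2.89e-12), the polo-like kinase PLK2 by 3.16 ± 0.19 (adjusted p = 6.21e-15). The mitochondrial reductase FDXR rose by 2.51, PHLDA3 by 2.42, BBC3 by 2.19 and the growth arrest gene GADD45A by 1.29. In the BCL2 family 4 of 13 genes rose and 1 fell (4 and 3 adjusted over the list alone), with BAX at 0.97 and PMAIP1 at 0.75, and the list did not pass (camera adjusted p = 0.148).

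Replication genes fell in 22 of 29 cases in the combination (25 adjusted over the list alone; median -0.49, camera adjusted p = 2.03e-24), with the uracil glycosylase UNG at -0.78 ± 0.10, FEN1 at -0.70 ± 0.10, MCM5 at -0.67 and the transcription factor E2F1 at -0.60. Mitotic genes rose in 18 of 30 cases (22 adjusted over the list alone; median 0.35, camera adjusted p = 3.83e-19), with TOP2A at 0.84 ± 0.08, the ubiquitin-conjugating enzyme UBE2C at 0.77, and DLGAP5 and the kinesin CENPE both at 0.64. Of 18 ATR-CHK1 checkpoint genes 3 fell (4 adjusted over the list alone; median -0.11, camera adjusted p = 0.014): CDC25A at -0.48, CLSPN at -0.47 and TIPIN at -0.48. Of 21 fork and recombination genes 4 fell (8 adjusted over the list alone; median -0.21, camera adjusted p = 0.00052, adjusted p = 0.0981 with an estimated correlation), among them EXO1 at -0.44, BLM at -0.40 and BRCA1 at -0.33. Ribosome biogenesis genes fell in 3 of 17 cases (12 adjusted over the list alone; median -0.22, camera adjusted p = 2.89e-07), with RRP12 at -0.62.

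ATF4 targets rose in 7 of 20 cases in the combination (9 adjusted over the list alone; median 0.48, camera adjusted p = 1.06e-07, adjusted p = 0.0422 with an estimated correlation), with ATF3 at 1.90, SESN2 at 1.64, DDIT4 at 1.32 and DDIT3 at 0.89. Immediate early genes rose in 5 of 12 cases (6 adjusted over the list alone; median 0.66, camera adjusted p = 2.95e-06), with EGR1 at 2.44, ARC at 2.13 and JUN at 1.19. Hypoxia genes rose in 7 of 22 cases (9 adjusted over the list alone; median 0.30, camera adjusted p = 1.98e-05), with ALDOC at 2.02, VEGFA at 1.01, PGK1 at 0.70 and BNIP3 at 0.61. Of 11 heat shock genes 3 rose (3 higher and 3 lower adjusted over the list alone), with HSPA1B (chromosome 6, 31827735 to 31830255) at 1.40 ± 0.13, while the list had a median of -0.04 and a mean of 0.21 and did not pass (camera adjusted p = 0.148). HSPA1B has a near-identical neighbour, HSPA1A, and how shared reads were divided is not given in the sources used here, so its value is uncertain.

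Of 16 sympathetic identity genes 4 fell and 1 rose in the combination (5 and 1 adjusted over the list alone; median -0.08, camera adjusted p = 0.0439, adjusted p = 0.0733 with an estimated correlation). Among those that fell were MYCN, HAND1 at -0.38 and MEIS1 at -0.36. Cholesterol synthesis passed upward with 1 of 22 genes called, STARD4 at 1.05 (1 adjusted over the list alone; camera adjusted p = 0.021, adjusted p = 0.271 with an estimated correlation). Neuronal differentiation passed upward with 1 of 20 called (2 adjusted over the list alone; camera adjusted p = 0.021, adjusted p = 0.327 with an estimated correlation). NRF2 targets passed downward with 1 of 15 called, GCLM at -0.70 (7 adjusted over the list alone; camera adjusted p = 0.00144, adjusted p = 0.123 with an estimated correlation). Among the remaining genes, FGFRL1 fell by 1.14, SGCD by 1.12, and SMAD3 and SYT2 both by 0.90. RNU4-82P, a small nuclear RNA pseudogene inside GOLGA1 (chromosome 9, 124887410 to 124887549), measured 3.18 higher, a value left uncertain by the many copies of this RNA and by its host gene.

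The combination called 865 genes, 476 higher and 389 lower (456 and 508 with library sizes alone as the scaling), of which 199 rose and 8 fell at least 2-fold. The calls of BRCA1 (without DMSO replicate 3 or combination replicate 1 or 2, adjusted p up to 0.0812) and TIPIN (without combination replicate 3, 0.0579) depended on single libraries. So did the lists of cholesterol synthesis and neuronal differentiation (each without DMSO replicate 3 or combination replicate 2 or 4, up to 0.157 and 0.119) and sympathetic identity (without DMSO replicate 2 or 3 or combination replicate 2 or 4, up to 0.0902). The cholesterol list also missed the threshold with no low-count filter (0.0644) and the sympathetic identity list in the fit of only the compared groups (0.0766).

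**Figure D4:**
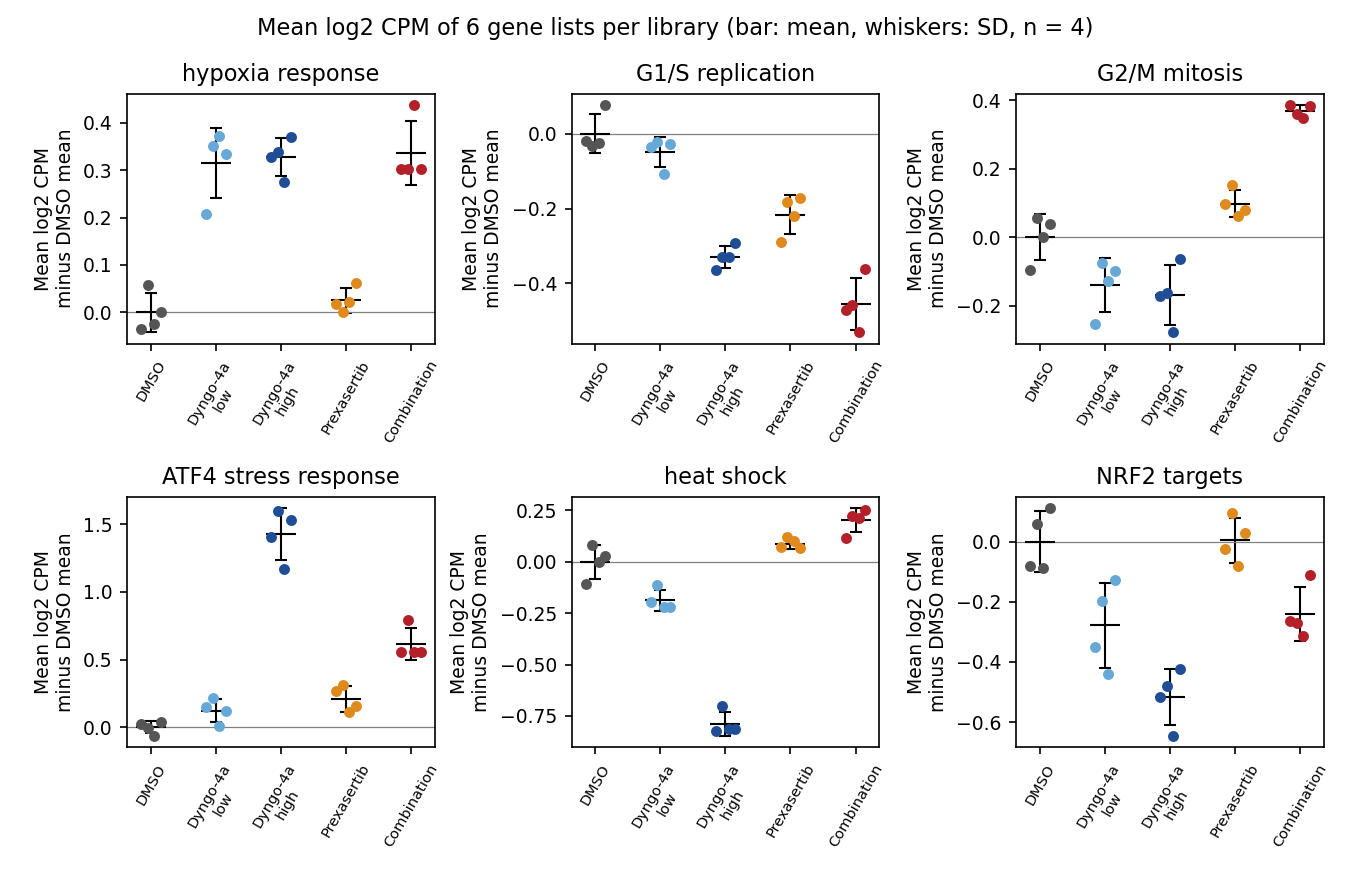
Mean log2 CPM of 6 gene lists in each library, minus the mean of the 4 DMSO libraries (y axis), by group (x axis); points are libraries, the bar is the mean and the whiskers are the SD of 4 libraries. Hypoxia genes lie above DMSO in both Dyngo-4a doses and the combination, mitotic genes lie above DMSO in the combination and below it in both Dyngo-4a doses, and heat shock genes are lowest in the high dose.

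Against prexasertib alone, the combination asked what Dyngo-4a adds, if the combination held the same dose of prexasertib. CDKN1A was higher by 2.21 ± 0.18, FDXR by 2.09, DDB2 by 1.81, BTG2 by 1.74, PLK2 by 2.23 ± 0.17 and PURPL by 2.37. Replication genes were lower in 8 of 29 cases (14 lower and 1 higher adjusted over the list alone; median -0.28, camera adjusted p = 3.91e-10), with UNG at -0.64 and E2F1 at -0.48. Mitotic genes were higher in 10 of 30 cases (18 adjusted over the list alone; median 0.25, camera adjusted p = 8.3e-14), with TOP2A at 0.56. Hypoxia genes were higher in 6 of 22 cases (10 higher and 1 lower adjusted over the list alone; median 0.31, camera adjusted p = 3.91e-06), with ALDOC at 1.55. Immediate early genes were higher in 5 of 12 cases (5 adjusted over the list alone; median 0.33, camera adjusted p = 3.9e-05). Ribosome biogenesis genes were lower in 4 of 17 cases (13 adjusted over the list alone; median -0.22, camera adjusted p = 3.91e-10). Sympathetic identity genes were lower in 4 of 16 cases (5 lower and 1 higher adjusted over the list alone; median -0.13, camera adjusted p = 0.0033), with MYCN at -0.50 ± 0.09.

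Further lists passed here with the preset correlation only. ATF4 targets were higher in 4 of 20 cases (7 adjusted over the list alone; camera adjusted p = 1.24e-05, adjusted p = 0.0846 with an estimated correlation). NRF2 targets were lower in 2 of 15 cases (4 adjusted over the list alone; camera adjusted p = 0.000179, adjusted p = 0.0846 with an estimated correlation). Cholesterol synthesis was higher for 1 of 22 genes (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00421, adjusted p = 0.202 with an estimated correlation). Neuronal differentiation was higher for 2 of 20 genes (2 adjusted over the list alone; camera adjusted p = 0.0203, adjusted p = 0.347 with an estimated correlation). GCLM was lower by -0.71 and HMOX1 by -0.97, FGFRL1 by -1.09, SYT2 by -0.84, SMYD5 by -0.81 and the receptor gene KIT by -0.76. The test called 472 genes, 329 higher and 143 lower, and 1374 with the replicate number as a block (695 and 679); DESeq2 gave 406 higher and 277 lower. Leaving out combination replicate 1 gave 309 genes. The calls of HMOX1 (without prexasertib replicate 1 or combination replicate 2, adjusted p up to 0.0802), and KIT (without combination replicate 3, 0.0535) depended on single libraries. The cholesterol list (without combination replicate 2, 0.0618) and the neuronal list (without prexasertib replicate 3 or combination replicate 2 or 4, up to 0.229; 0.0927 with no low-count filter) did as well.

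Against the low dose of Dyngo-4a, the combination asked what prexasertib adds, if the combination held that dose. Mitotic genes were higher in 23 of 30 cases (27 adjusted over the list alone; median 0.51, camera adjusted p = 4.4e-40), with TOP2A at 0.85 ± 0.08 and CDC20 at 0.81 ± 0.12. BBC3 was higher by 1.81, GDF15 by 1.47 and GADD45A by 1.19. Replication genes were lower in 19 of 29 cases (23 adjusted over the list alone; median -0.40, camera adjusted p = 9.27e-25), with UNG at -0.69 and MCM4 at -0.60. Immediate early genes were higher in 5 of 12 cases (6 adjusted over the list alone; median 0.60, camera adjusted p = 9.25e-09), with EGR1 at 2.15. ATF4 targets were higher in 7 of 20 cases (9 adjusted over the list alone; median 0.31, camera adjusted p = 1.22e-08). Heat shock genes were higher in 4 of 11 (5 adjusted over the list alone; median 0.15, camera adjusted p = 2.05e-06), with HSPA1B at 1.73. Sympathetic identity genes were lower in 4 of 16 cases (5 adjusted over the list alone; median -0.10, camera adjusted p = 0.00824), with MYCN at -0.44 and HAND1 at -0.33. ATR-CHK1 genes were lower in 2 of 18 (2 adjusted over the list alone; median -0.12, camera adjusted p = 0.024), with CLSPN at -0.49. Ribosome biogenesis genes passed downward with 0 of 17 called (5 adjusted over the list alone; median -0.20, camera adjusted p = 2.05e-06).

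With the preset correlation only, fork and recombination genes were lower (5 of 21, 7 adjusted over the list alone; camera adjusted p = 6.96e-05, adjusted p = 0.0565 with an estimated correlation). Neuronal differentiation passed upward with 0 of 20 called (1 adjusted over the list alone; camera adjusted p = 0.00496, adjusted p = 0.273 with an estimated correlation). The BCL2 family was higher for 2 of 13 genes (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0232, adjusted p = 0.185 with an estimated correlation). PLK2 was higher by 2.40, and 3 genes with many near-identical copies, whose values are therefore uncertain, were higher too: the histone gene H2BC8 (chromosome 6, 26215159 to 26216692) by 2.46, RNU4-82P by 2.53 and RNU6-11P by 2.23. SGCD, JPH1 and CLMP were lower by -1.27, -1.05 and -0.97. The test called 528 genes, 371 higher and 157 lower (329 and 256 with library sizes alone as the scaling), and 1149 with the replicate number as a block (609 and 540). The call of HAND1 was lost without low-dose replicate 1, 2 or 4 or combination replicate 1, 2 or 3 (adjusted p up to 0.141). That of the ATR-CHK1 list was lost without low-dose replicate 2 or 4 or combination replicate 3 (up to 0.0616). Those of the neuronal (0.0686) and BCL2 (0.0651) lists were lost without low-dose replicate 3.

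The interaction asked whether the effect of prexasertib differed in the presence of Dyngo-4a. It took the low dose and prexasertib at 2 nM as the matching single treatments. The labels do not state that the combination held these doses. The change beyond the sum of both single changes was positive for mitotic genes. The kinase PLK3 was called higher at 1.79 ± 0.31 (adjusted p = 0.00211), BBC3 at 1.21 ± 0.22, DDB2 at 1.21 ± 0.20, GADD45A at 0.91 ± 0.15 and PLK2 at 1.47 ± 0.28 (adjusted p = 0.0047). All 30 mitotic genes had a positive value (median 0.40, camera adjusted p = 2.78e-29), 1 of them called, TOP2A at 0.57, and 24 adjusted over the list alone. Heat shock genes passed upward (2 of 11 called, HSPA1B at 1.31 ± 0.18 and DNAJB1 at 0.96 ± 0.17; 3 adjusted over the list alone; median 0.16, camera adjusted p = 0.000195). Immediate early genes did too (0 of 12 called, 3 adjusted over the list alone; median 0.53, camera adjusted p = 0.000195).

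Replication genes passed downward in the interaction (0 of 29 called, 2 adjusted over the list alone; median -0.18, camera adjusted p = 1.44e-06). Ribosome biogenesis (0 of 17 called, 0 adjusted over the list alone; median -0.23, camera adjusted p = 3.14e-07) and sympathetic identity genes (0 of 16 called, 2 adjusted over the list alone; median -0.14, camera adjusted p = 0.00064) passed downward as well. The lists of ATF4 targets (2 of 20 called, 5 adjusted over the list alone) and neuronal differentiation (0 of 20 called, 0 adjusted over the list alone) passed upward with the preset correlation only (camera adjusted p = 0.000433 and 0.0133, adjusted p = 0.223 and 0.416 with an estimated correlation). SESN2 stood at 1.21 and ATF3 at 1.16. CDKN1A at 1.03 ± 0.26 (adjusted p = 0.143), MYCN at -0.50 ± 0.13 (0.104) and UNG at -0.55 ± 0.14 (0.0705) were not called. H2BC8 stood at 1.84 and ETV5 at 1.81, and the 2 genes called lower were the potassium channel gene KCNK2 at -0.78 and DTL, a ubiquitin ligase subunit of S phase, at -0.69.

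The interaction called 39 genes, 37 higher and 2 lower, and 72 with DESeq2 and 65 with no low-count filter. CDKN1A passed with both of these (adjusted p = 0.00496 and 7.8e-05), with limma-voom (0.0264), and without DMSO replicate 3 or low-dose replicate 1 (down to 0.00648). MYCN passed with DESeq2 (0.0182), no filter (0.0484) and library sizes alone (0.0273) and without DMSO replicate 4 or combination replicate 4 (down to 0.0341). UNG passed with DESeq2 (0.0197) and library sizes alone (0.0287) and without combination replicate 4 (0.00516). With the replicate number as a block CDKN1A (0.00156), MYCN (8.57e-05) and UNG (0.000537) all passed, though the numbers did not meet the rule for pairing here. The calls of ETV5 and ATF3 were lost in 12 and 10 of 16 refits that each left out 1 library (adjusted p up to 0.129 and 0.144). These were, for both genes, DMSO replicates 2 and 3, low-dose replicates 1, 3 and 4, prexasertib replicate 3 and combination replicate 3. For ETV5 they were also DMSO replicate 1, low-dose replicate 2, prexasertib replicates 1 and 2 and combination replicate 2. For ATF3 they were also DMSO replicate 4, prexasertib replicate 4 and combination replicate 1. The calls of both were also lost with limma-voom (0.0992 and 0.0859), and that of ATF3 with library sizes alone (0.0654) and in the fit of only the compared groups (0.0609). TOP2A was lost without low-dose replicate 1 (0.0521) and KCNK2 without combination replicate 2 (0.0557). The neuronal list was lost without DMSO replicate 4, low-dose replicate 3, prexasertib replicate 3 or combination replicate 2 (up to 0.202) and with no low-count filter (0.203).

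In all comparisons together, 5 lists passed in none of the 8 comparisons. Their lowest camera adjusted p was 0.0538 for chaperones of the endoplasmic reticulum (low dose), 0.0614 for mesenchymal identity (low dose), 0.135 for metallothioneins and iron (combination), 0.139 for interferon response (high against low dose) and 0.417 for clathrin endocytosis (high against low dose). Targets of the aryl hydrocarbon receptor, NF-kB inflammation genes and Schwann cell markers had 3, 3 and 2 tested members, too few for the list test, and the genes of the mitochondrial genome were not analysed here. Of the 67 passes over the lists reported here and all comparisons, 41 held with an estimated correlation. Each pass of camera whose p with an estimated correlation is not printed is among these 41.

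The 2 subsets of replicates seen in the principal components were also fitted apart, an alternative chosen after seeing the data. Within replicates 1 and 3, and within replicates 2 and 4, edgeR called 2230 and 2221 genes for the high dose, 35 and 4 for the low dose, 5 and 0 for prexasertib, and 911 and 221 for the combination against DMSO. For the combination against prexasertib it called 488 and 104, against the low dose 485 and 143, for the interaction 30 and 1, and for the high against the low dose 1457 and 1588.

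Fold changes of different treatments were compared across the 13729 genes, which are not independent replicates, and every comparison shared the DMSO libraries. For the high and low doses Pearson's r was 0.461, against 0.508 on average in simulated unchanged groups that shared their controls, and 0.168 on average with the DMSO libraries split between the comparisons. The covariance was 0.0649 against a simulated 0.0309. The same values for prexasertib and the combination were 0.509, 0.506 and 0.130 (covariance 0.0565 against 0.0308), for the low dose and the combination 0.490, 0.501 and 0.140 (0.0582 against 0.0306), and for the high dose and the combination 0.479, 0.506 and 0.265 (0.0999 against 0.0308). Genes called in both the high and the low dose were 23 higher and 11 lower in both and 1 opposite, where independent lists would share 3.12 and 1.40. The high dose and the combination shared 229 higher, 231 lower and 26 opposite calls, where independent lists would share 59.5 and 49.3. The low dose and the combination shared 20 higher and 2 lower calls, where independent lists would share 0.867 and 0.312. Simulated unchanged groups that shared their controls had 0 such shared calls on average for each of these 3 pairs. Groups simulated without change have few called genes to share, so this value was close to fixed in advance. It does not show how many shared calls the common DMSO libraries give between treatments that do change genes. The values for independent lists leave out the shared libraries as well. The simulations also ignore the pairing by replicate number.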

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

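The tests of divided copies and of nuclear RNA for the histone and small nuclear RNA genes, the length-matched test of the histone genes, the counts over splits that part the replicate pairs and these 2 gene classes themselves were chosen only after the results were seen. Of 452 groups of 4 libraries tested, 22 (4.87%) held a library far from the other 3, where chance gives about 1 in 20. The values below are that library's gap to its nearest neighbour as a share of the group's range.

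Among genes, in the high dose the gap was 0.896 for ALDOC (replicate 1 lowest), 0.980 for GCLM and 0.875 for SESN2 (replicate 2 highest), and 0.949 for HMMR (replicate 3 lowest). In the combination it was 0.8996 for FGFRL1 (replicate 4 lowest), 0.839 for DDIT3 (replicate 3 highest) and 0.922 for E2F1 (replicate 2 highest). In DMSO it was 0.969 for GCLM (replicate 2 highest), 0.905 for PHLDA3 (replicate 4 highest) and 0.833 for H2BC8 (replicate 1 lowest). In the low dose it was 0.830 for GCLM (replicate 3 lowest) and 0.831 for SYT2 (replicate 2 lowest).

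Among list means, in DMSO the gap was 0.928 for immediate early genes (replicate 3 lowest), 0.877 for replication genes (replicate 4 highest) and 0.8295 for chaperones of the endoplasmic reticulum (replicate 2 highest). In the combination it was 0.974 for ATF4 targets (replicate 2 highest), 0.8315 for clathrin endocytosis (replicate 3 lowest) and 0.993 for hypoxia genes (replicate 3 highest). In the low dose it was 0.834 for replication genes (replicate 3 lowest) and 0.8795 for aryl hydrocarbon receptor targets (replicate 3 highest). For prexasertib it was 0.834 for chaperones of the endoplasmic reticulum (replicate 4 lowest), and in the high dose 0.885 for heat shock genes (replicate 2 highest). Combination replicate 3, high-dose replicate 2 and low-dose replicate 3 had 3 such values each.

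By the interaction test the change in the combination differed from the sum of both single changes for 14 named genes and 8 lists. The doses inside the combination are not given, so another dose of either drug there cannot be told apart from an interaction. The genes and lists stand here because they passed this test, so their numbers are no further support. The log2 differences were -0.78 for KCNK2, 1.21 for BBC3, 0.91 for GADD45A, 1.21 for SESN2, 0.57 for TOP2A, 0.96 for DNAJB1, 1.21 for DDB2, -0.69 for DTL, 1.47 for PLK2, 1.16 for ATF3, 1.79 for PLK3, 1.31 for HSPA1B, 1.81 for ETV5 and 1.84 for H2BC8. The median differences were -0.18 for replication genes, 0.40 for mitotic genes, -0.23 for ribosome biogenesis, 0.21 for ATF4 targets, -0.14 for sympathetic identity, 0.17 for neuronal differentiation, 0.53 for immediate early genes and 0.16 for heat shock genes; the lists of ATF4 targets and neuronal differentiation missed the threshold with an estimated correlation (adjusted p = 0.223 and 0.416).

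Other splits of the same libraries were fitted as well. As many genes as in the real split were called in 1 of 35 splits, the real one, for each comparison named next. These were the high dose (3456, highest other 1), the low dose (36, 1) and the high against the low dose (2767, 0). The combination was among them against DMSO (865, 3), against prexasertib (472, 2) and against the low dose (528, 0). For the high dose and the combination against DMSO this excludes a chance split, provided their libraries are not paired. For the others the replicate number was read as pairing, which all splits ignore. Only 8 splits part all pairs there, too few for a share under 0.05, so a chance split cannot be excluded by such a share. For prexasertib, whose real count was 0, 35 of 35 splits called as many, and the highest other, 16, was the split of replicates 1 and 3 against 2 and 4; with the replicate number as a block the real comparison called 23. For the interaction 2 of 100 draws called as many as 39, the real one included. The other called 202, which points to a structure of the samples: it held the 4 combination libraries together as 1 group. The draws mix libraries of all groups compared, so they also break up the differences between the single treatments. They therefore cannot decide whether a chance split gives this interaction count.

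By the number of gene lists past the threshold, all splits exclude a chance split only for the combination against DMSO, provided its libraries are not paired. There 1 of 35 splits gave as many (13 lists, highest other 11). Against the low dose 1 of 35 splits also gave as many (12, highest other 11), but there the replicate number was read as pairing. All splits ignore the pairing, so they cannot exclude a chance split there. By all splits, which ignore the pairing by replicate number, it is not excluded for the high dose (4 of 35; 9, highest other 10), the low dose (4 of 35; 6, highest other 6), prexasertib (4 of 35; 7, highest other 11), the combination against prexasertib (4 of 35; 11, highest other 11), the high against the low dose (5 of 35; 8, highest other 10) and the interaction (7 of 100 draws; 9, highest other 12).

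Where the replicate number pairs the libraries, 8 of the 35 splits part all 4 pairs as the real one does, too few for a share under 0.05. Among these 8 the number of lists and the highest other were 6 and 6 for the low dose, 7 and 6 for prexasertib, 11 and 11 for the combination against prexasertib, 12 and 11 against the low dose, and 8 and 8 for the high against the low dose. With the replicate number as a block they were 7 and 6, 7 and 8, 11 and 12, 12 and 11, and 8 and 9 in the same order, and the numbers of genes were 260 and 1, 23 and 0, 1374 and 2, 1149 and 0, and 3980 and 0. The 27 other splits leave some pairs on one side and gave at most 6, 11, 11, 10 and 10 lists without the block.

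For single lists past the threshold, the splits with a camera p as small as the real one, in either direction and the real one included, reached 5% as follows. In the high dose they were 11 of 35 for mitotic genes, 6 for cholesterol synthesis, 3 for NRF2 targets and 2 for hypoxia genes. In the low dose they were 4 for mitotic genes, 3 for NRF2 targets and 2 for cholesterol synthesis, and with prexasertib 2 for ATF4 targets. In the combination against DMSO they were 11 for cholesterol synthesis, 5 for fork and recombination genes, 5 for neuronal differentiation, 3 for NRF2 targets and 2 for ATR-CHK1 genes. Against prexasertib they were 10 for neuronal differentiation, 7 for cholesterol synthesis, 3 for NRF2 targets and 2 for ATF4 targets. Against the low dose they were 7 for neuronal differentiation, 4 for fork and recombination genes, 3 for ATR-CHK1 genes, and 2 each for ribosome biogenesis, sympathetic identity and the BCL2 family. For the high against the low dose they were 9 for NRF2 targets, 5 for cholesterol synthesis and 4 for the BCL2 family. For the interaction they were 23 of 100 draws for replication genes, 19 for neuronal differentiation, 11 for ATF4 targets and 5 for immediate early genes. By all splits, which ignore the pairing by replicate number where it holds, a chance split is not excluded for these. For mitotic genes in the interaction 1 of 100 draws, the real one, gave a p as small. These draws also break up the differences between the single treatments, so they cannot decide on an interaction.

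Replicates 1 and 3 lay apart from replicates 2 and 4 on the second principal component in 5 of 5 groups, and by total count and MALAT1 share in 4 of 5 each; a term for these subsets called 2625 genes. After all libraries were thinned to the smallest total 2402 genes were called, 91.5% as many, and 2239 genes were called at both depths, which argues against depth as the whole cause. Spearman's rho across genes between the difference and GC content was -0.0503 with differing signs by group, which argues against GC content. With transcript length rho was 0.224 (0.0900 to 0.181 within groups), so length stays open, and the labels name no batch. No biological explanation was tested.

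Counts of histone genes in these 3′ mRNA libraries were higher in the combination than in DMSO. Of 43 genes 23 rose and 0 fell, with a median log2 fold change of 1.34. Whether these counts follow all transcripts of the histone genes was not tested. Divided copies would lower some members, and 0% of the called members were lower. More nuclear RNA, read from MALAT1, would raise them in the high dose too, where their median was -0.397 (-0.855 to -0.0594). There 13 were called lower and 3 higher. A fall from another cause could hide such a gain, so these values cannot decide on nuclear RNA. The 20 other genes nearest to each histone gene in transcript length had a median of 0.0873 (upper end 0.175), below 0.669, which is 50% of the histone median, and this argues against a gain of short transcripts. With prexasertib alone 37 of the 43 had a positive value and 0 were called, where edgeR called 0 among all genes. Their median was 0.386 (0.245 to 0.573, camera p = 0.00107 with an estimated correlation), so a smaller shift upward also stood without Dyngo-4a. In the low dose their median was -0.25. In the interaction it was 0.986, with 41 positive (camera p = 1.94e-06 with an estimated correlation). The rise was thus larger than the sum of both single changes, with the doses inside the combination not given. Prexasertib, alone or with Dyngo-4a, is the biological alternative that the design gives, and it stays untested.

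Counts of small nuclear RNA genes also lay higher in the combination: 14 of 50 rose and 1 fell, and 29 were positive. Their median was 0.32, with an interval that spans no change (-0.0455 to 0.628, camera p = 0.0399 with an estimated correlation). Whether these counts follow all small nuclear RNA was not tested. Of the called members 6.67% were lower, which argues against divided copies. Their median in the high dose was -0.0452 (-0.191 to 0.286), too wide to decide on nuclear RNA. The 101 other genes with transcripts as short had a median of 0.212 (0.109 to 0.340), so a gain of short transcripts could account for the shift in the combination. With prexasertib alone their median was 0.0661 (-0.0328 to 0.265). The design gives the treatment as the biological alternative, which stays untested.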

How the results depend on the processing

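The term for replicate subsets and the fits within them were chosen after seeing the data. Under the settings chosen before the data were examined 170 of 211 named-gene results kept direction and side of the threshold in all, 21 fell short and 14 passed in at least 1, and 6 changed sign in at least 1, none of them called; of 67 list results 39 held in all and 28 fell short in at least 1, 26 of them with an estimated correlation. Where not said otherwise, the cause was not tested. Many of these genes were named for large changes or a small p in these same libraries, and the list results are those past camera. Their shares therefore do not say how other genes or lists would hold.

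Counts of called genes moved by over 1.5 times as follows. DESeq2 called 6 genes for prexasertib and 72 for the interaction. With no low-count filter the counts were 62 (low dose), 12 (prexasertib) and 65 (interaction), and with the compared groups alone 2 (prexasertib). With the replicate number as a block they were 260 (low dose), 23 (prexasertib), 1976, 1374 and 1149 (combination against DMSO, prexasertib and low dose) and 167 (interaction, 131 higher and 36 lower); for the combination against DMSO they were 973 higher and 1003 lower. With the term for replicate subsets they were 73, 4, 1427, 909, 829 and 93 in the same order. Within replicates 1 and 3, with fewer samples, they were 2230 (high dose), 5 (prexasertib) and 1457 (high against low dose). Within replicates 2 and 4 they were 2221, 4, 221, 104, 143, 1 and 1588 (high dose, low dose, the 3 combination comparisons, interaction, high against low dose). Leaving out 1 library gave 14 to 30 (low dose), 0 to 2 (prexasertib) and 309 to 474 (combination against prexasertib).

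With the replicate number as a block, where the numbers did not meet the rule for pairing, DNM2 passed in the high dose (adjusted p = 0.0390), and CDKN1A (0.00156), MYCN (8.57e-05) and UNG (0.000537) passed in the interaction. Apart from these and the calls given in the report for the low dose and prexasertib, the block changed no call of a named gene, and no list past the threshold lost its pass.

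In the fit within replicates 1 and 3, 17 named-gene and 6 list results fell short of the threshold, and within replicates 2 and 4 these were 55 and 6. Some of these lists are among those counted above. In each fit where a sign changed the gene was not called; only CHEK1 in the high dose was called with all libraries. MYCN in the low dose measured 0.0160 with library sizes alone, 0.000396 within replicates 2 and 4, and -0.0496 to 0.0515 without 1 library. Within replicates 1 and 3 CHEK1 measured -0.0229 (high dose), -0.0241 (low dose) and -0.0556 (combination), DNM1 -0.0887 and DNM3 -0.0468 (high dose), and MUS81 0.00622 (prexasertib). Within replicates 2 and 4 MUS81 measured 0.000417 (low dose) and CHEK1 0.120 (prexasertib). Without 1 library MUS81 ranged from -0.166 to 0.00697 (high dose) and -0.0884 to 0.0571 (prexasertib), DNM1 from -0.128 to 0.151 (high dose), and CHEK1 from -0.0903 to 0.0588 (prexasertib) and -0.0474 to 0.124 (combination).

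Correlations of fold changes fell when DMSO libraries were not shared, in part by construction. With replicates 1 and 2, 1 and 3, or 1 and 4 on one side they were 0.200, 0.121 and 0.184 (high and low dose), 0.168, 0.0738 and 0.148 (prexasertib and combination), 0.176, 0.0875 and 0.158 (low dose and combination) and 0.290, 0.228 and 0.278 (high dose and combination). In each pair the lowest value had replicates 1 and 3 on one side. That split also sets the difference between the replicate subsets against itself, which lowers r. The fall is therefore not only the loss of shared libraries. With a filter of 1 CPM prexasertib and combination gave 0.523. Depth limits genes near the floor, and at this size 1.5-fold changes were recovered in 43.3% of simulated cases for the combination and 16.4% for the interaction.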

Other observations

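The gene classes here and the test of TFRC were chosen after values were seen; the test of the proteasome subunits was written before its result. HEXIM1, which encodes an inhibitor of transcription elongation, rose in the combination (log2 fold change 1.34 ± 0.10, adjusted p = 2.82e-12) and differed in the interaction (0.96, adjusted p = 0.000335). Among near-identical copies, with uncertain values, H4C5 rose by 3.07, RNU4-2 by 2.32, RNU4-1 by 3.12 and RNVU1-31 by 2.95 in the combination, and H2BC9 fell by 1.56 in the high dose.

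As a hypothesis from PSMC1, other proteasome subunit genes may be lower in the low dose too. Without PSMC1 and PSMD11, 29 subunit genes had a median log2 fold change of -0.17 with 2 positive and 0 called by edgeR, which called 36 among all genes and 1039 at an unadjusted p under 0.05 (camera p = 1.16e-12, and p = 0.0131 with an estimated correlation). In the high dose 18 fell (median -0.41, p = 0.00875 with an estimated correlation), and in the combination the p was 0.173 with an estimated correlation.

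As a second hypothesis, iron withdrawal might account for the hypoxia genes in the low dose. It would stabilise HIF, the factor of the hypoxia response, and the transcript of TFRC, the transferrin receptor. A rise of TFRC alone does not tell iron withdrawal apart from other causes. TFRC rose by 0.42 in the low dose (adjusted p = 0.0178) and by 0.34 in the high dose (adjusted p = 0.00348) and measured 0.28 in the combination (adjusted p = 0.0554). The list of metallothioneins and iron, which holds TFRC, did not pass camera in the low dose (adjusted p = 0.673).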
